A study of Drosophila melanogaster with 4 samples.

How the data were processed

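The data are 1-colour Affymetrix Drosophila arrays of whole larvae of the third instar raised at 25 °C. Per the labels' protocols, larvae from crosses of the C564-Gal4 driver with UAS-GFP or UAS-Gyc76C were homogenized in Trizol, total RNA was purified with the RNeasy kit, and biotin-labelled cRNA was hybridized. There were 2 arrays per genotype, and the labels call them biological replicas. Samples were grouped by the genotype in their titles.

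The deposited values are probe set intensity values on a linear scale, made by the authors with MAS5 per the submitters' processing notes, which give no version. The genome build behind the array annotation is not given in the sources used here. The values were positive and ran from 0.358 to 48176 over the 4 arrays, and the 2% trimmed mean of each array was 499.4 or 499.5, so the authors' values had been scaled to a common mean. MAS5 gives a signal also to probe sets that detect nothing, and detection calls were not used here. Low signals therefore scatter widely on the log2 scale, and fold changes of dim probe sets are uncertain. A common trimmed mean does not fix the median, which is why other scalings were tried.

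The table held 18952 probe sets, 183 of them control probe sets, whose names start with AFFX. Of the others, 13646 had 1 gene symbol in the platform annotation, 402 had several and 4721 had none and are unnamed here. Entrez numbers of 13543 probe sets with 1 gene were found in the RefSeq gene table of assembly Release 6, and 0 of these symbols differed, so symbols were kept as annotated. They cover 11981 different genes. No gene was named from a probe set with several symbols, except that the overexpressed gene was followed through the probe sets annotated to Gyc76C and CG42637 together, the brightest of them standing for the gene. Antimicrobial peptide genes without a probe set of their own here, such as DptA, AttA, CecA1 and Dro, were not analysed here. Every column of values belonged to a sample.

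Control probe sets were left out, signals were put on the log2 scale without a pseudocount, and probe sets were kept if their mean signal over the 4 arrays was at or above the 40th percentile (46.3), which left 11261. The authors' scaling was kept. Genotypes were compared with limma (version 3.58.1 in R 4.3.3), with lmFit and eBayes with a mean trend in the prior variance, and p-values are two-sided and adjusted by the Benjamini-Hochberg method over the probe sets tested. A probe set was called past the threshold at an adjusted p under 0.05. The fit had 2 residual and 4.64 prior degrees of freedom. Where both arrays of a genotype were under 46.3, the fold is given as at least the other genotype's mean over that level. Folds are ratios of geometric means, whereas the means ± SD are arithmetic. Where 1 array alone was under it, that signal was raised to 46.3 for the fold, which is then also given as at least so much; log2 fold changes are as measured. Values are given as mean ± SD over the 2 arrays of a genotype, and standard errors are those of the log2 fold change.

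For gene lists, each gene was represented by its brightest probe set. There were 49 lists, among them Toll-responsive and Imd-responsive effectors, pathway components, cGMP signalling, ecdysone response genes, cuticle genes, metabolic and housekeeping groups, and markers of the tissues and blood cells that a whole larva holds. The 45 lists with at least 3 tested genes were compared with the other genes by camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the arrays and the rotation test fry were run beside it. With an estimated correlation camera has only the 2 residual degrees of freedom of the arrays and little power. A list that does not pass it is therefore not evidence against a shift. Members past the threshold were counted over all genes tested and again adjusted over the list alone. The lists were compiled from general knowledge of fly biology and overlap in part.

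Genes named in the text follow a rule. It takes the overexpressed gene, then the 12 genes that rose and the 12 that fell with the largest log2 fold changes among those past the threshold, with groups that do not overlap and with 1 symbol. It then takes up to 4 called members of each list with the largest changes, or up to 2 members where none is called, and the antimicrobial peptide genes Drs, Mtk, DptA, AttA, CecA1, Def and Dro where they have a probe set. Genes that the report names outside the rule are said to be so, and in the closing section genes are named as members of the group tested there. The groups, the test, the lists, this rule and the alternatives listed below, except those named there as added, were chosen before the data were examined.

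A count of probe sets in which both arrays of a genotype lay at least 2-fold on 1 side of both arrays of the other was made for the real split of the 4 arrays and for the other 2 splits. It has no p-value, since 3 splits cannot give a permutation p under 0.05.

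The fit was tested on simulated data for this comparison, with 11261 probe sets of which 200 were changed. It recovered 8% of 2-fold and 36% of 4-fold changes, with 0 calls among unchanged probe sets and 0 when nothing was changed. Far fewer probe sets were changed than the 2771 called in the data, which makes the adjustment stricter, so these rates do not carry over. The simulated noise was independent between probe sets, so deviations shared across an array were not tested. Camera gave p = 2.65e-31 for a simulated list of 20 genes moved 2-fold and p = 0.327 for an unmoved one, and p = 0.0061 for the moved list with an estimated correlation.

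The alternatives were quantile normalization, centring of each array on its median, 16 or 64 added before log2, no filter or a filter at the 60th percentile, the replicate number as a block, each array left out in turn, a variance model without trend or with robust estimation, an adjusted p under 0.1, a further threshold of 2-fold, signals under 32 raised to 32, the mean over a gene's probe sets, and folds of 1.5 and 3 in the count over pairs. Raising signals under 46.3 to that level and the recount of calls per gene list were added after the data were seen. When 1 array is left out, the lone array of a genotype is assumed to vary like the other genotype. Such a fit has fewer residual degrees of freedom, so a call can end although the fold change stays.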

Results

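Gene expression was measured in whole Drosophila melanogaster larvae of the third instar, raised at 25 °C, with 1-colour Affymetrix arrays. In the control larvae the C564-Gal4 driver switched on a GFP transgene. In the experimental larvae the same driver switched on Gyc76C, a transmembrane receptor guanylate cyclase, which the labels place in the fat body, the larval organ of fat storage and of humoral immunity. Each genotype had 2 arrays, described as biological replicas, so all 4 arrays enter the 1 comparison that the design allows. Across 11261 tested probe sets the 2 GFP arrays correlated at r = 0.966 and the 2 Gyc76C arrays at r = 0.968, whereas pairs of different genotype correlated at 0.88 to 0.91. The first principal component held 73.9% of the variance and separated the genotypes, with scores of -43.6 and -54.8 for GFP and 55.8 and 42.6 for Gyc76C. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.21.

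Signals had been scaled to a common trimmed mean of 499.5 on 3 arrays and 499.4 on the Gyc76C replicate 2 array. The median log2 signal of tested probe sets was nevertheless 0.16 lower in Gyc76C larvae (shift -0.16), so medians of the gene lists past the camera threshold are given as measured and after centring each array on its median. Hybridization control probe sets shifted by -0.62 and poly-A control probe sets by -0.32 between the genotypes in the same direction, with hybridization control means of 9.78, 9.82, 8.86 and 9.49 on the GFP replicate 1, GFP replicate 2, Gyc76C replicate 1 and Gyc76C replicate 2 arrays. The ratio of 3′ to 5′ signal is a sign of RNA quality. For eIF-4a it was 4.04 and 4.06 in the GFP samples and 3.12 and 3.61 in the Gyc76C samples. For actin it was 1.18 and 1.2 against 1.08 and 1.08, and for GAPDH 1.82 and 2 against 1.64 and 1.85.

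The overexpressed gene was measured first, as a check of the labels. The brightest probe set annotated to Gyc76C, which carries the symbol CG42637 as well, had a signal of 987.5 ± 84.1 in GFP larvae and 18521 ± 3500 in Gyc76C larvae (mean ± SD, n = 2 each). It was thus 18.6-fold higher with the Gyc76C transgene (log2 fold change 4.22, SE 0.17, limma adjusted p = 5.79e-05), and both Gyc76C arrays lay above both GFP arrays. A second tested probe set with the same annotation was dim at 78.4 ± 19.1 and 20 ± 14.9 and did not pass the threshold (log2 fold change -2.19, SE 0.81, adjusted p = 0.0951). The position of each probe set relative to the transgene is not given in the sources used here.

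The comparison of Gyc76C with GFP larvae asks which transcripts differ when the cyclase is overexpressed. Secreted immune peptides of the Bomanin family, the antimicrobial peptide gene Mtk and many cuticle protein genes were higher in Gyc76C larvae. The salivary glue genes Sgs3, Sgs5 and ng3 were lower by 47.3-fold to 94.2-fold, and ecdysone-responsive genes such as Eig71Ee were lower too. Genes of the mitochondrial ribosome shifted upward as a group by a median log2 fold change of 0.57, and proteasome genes shifted downward by a median of -0.47. Neither shift passed camera with an estimated correlation (adjusted p = 0.509 and 0.826), and 0 proteasome genes were called by limma without a mean trend in the variance. By limma, 2771 of 11261 probe sets (24.6%) passed an adjusted p of 0.05, 1271 of them higher and 1500 lower in Gyc76C larvae. Taking the brightest probe set of each gene, 2375 of 9259 genes passed, 1078 higher and 1297 lower. A change of at least 2-fold was reached by 620 of the higher and 753 of the lower probe sets, and of at least 10-fold by 49 in each direction. The share of calls that were higher was 45.9%, against 62.7% with arrays centred on their median and 54.8% after quantile normalization. The count was 1204 without Gyc76C replicate 1 (575 higher and 629 lower) and 1241 without a mean trend in the variance, and without Gyc76C replicate 2 there were 752 higher.

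**Figure D1:**
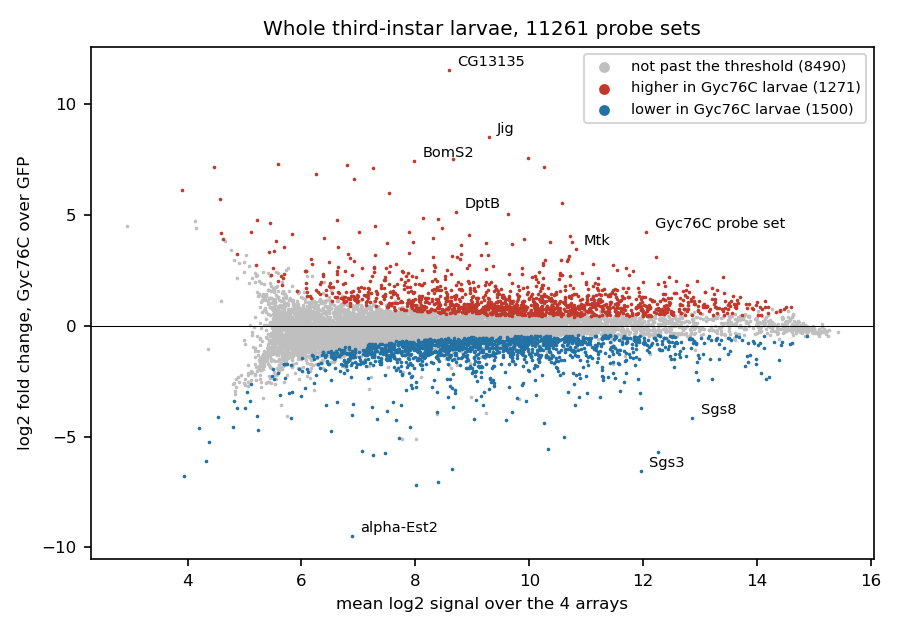
Log2 fold change of Gyc76C over GFP larvae (vertical axis) against the mean log2 signal over the 4 arrays (horizontal axis), 1 point per tested probe set. Red points mark the 1271 probe sets past the threshold with higher signal in Gyc76C larvae and blue points the 1500 with lower signal; CG13135, Jig and BomS2 lie far above 0, and alpha-Est2, Sgs3 and Sgs8, the last chosen after its values were seen, far below.

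Immune effector genes gave some of the largest rises. BomS2, a short secreted peptide of the Bomanin family, had a signal of 19.4 ± 4.56 in GFP larvae and 3368 ± 767 in Gyc76C larvae (n = 2 each), at least 71.7-fold higher (log2 fold change 7.44, SE 0.26, adjusted p = 3.82e-05). BomBc2, BomS5 and BomT2 were at least 17.5-fold, 26-fold and 11.2-fold higher, where "at least" sets a gene with both arrays of a genotype under a signal of 46.3 at that level. Metchnikowin (Mtk), an antifungal peptide gene, rose 10.9-fold from 559 ± 183 to 5979 ± 1040 (SE of the log2 fold change 0.24, adjusted p = 0.000455). Of 14 measured genes in the list of Toll-responsive effectors, 9 rose, 1 fell and 4 were not past the threshold, with 10 rising and 1 falling when adjusted over the list alone. The list's median log2 fold change was 1.47, or 1.63 with centred arrays, and it stood above other genes by camera (adjusted p = 4.08e-05). That call was lost, at adjusted p = 0.658, with an estimated correlation, and 2 members fell without GFP replicate 1 or Gyc76C replicate 2, after quantile normalization and with the replicate block.

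Drosomycin (Drs), the classical readout of Toll signalling, did not pass the threshold in the fit reported here. Its signals were 2310 and 7860 in GFP larvae and 9320 and 12700 in Gyc76C larvae (log2 fold change 1.35, SE 0.51, adjusted p = 0.101). The value rests on the spread of the GFP arrays, since the log2 fold change was 2.24 without GFP replicate 2 (adjusted p = 0.000189) and 0.47 without GFP replicate 1 (adjusted p = 0.125). With the replicate number as a block Drs did pass (log2 fold change 1.35, adjusted p = 0.00806). The member that fell was Drsl2, a drosomycin-like gene with a log2 fold change of -3.35 (adjusted p = 0.00444), and its relative Drsl5 had -3.94 with an SE of 1.63 (adjusted p = 0.123). BomS6 at 2.24, BomS4 at 1.58, SPE at 1.10 and IM33 at 0.50 completed the members that rose. Drsl2, Drsl5, BomS6, BomS4 and IM33 were singled out after their values were seen.

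Effectors of the Imd pathway, which responds mainly to Gram-negative bacteria, moved in both directions. Diptericin B (DptB) rose 35.4-fold, from 75.8 ± 39.9 to 2767 ± 1700, and the recognition protein gene PGRP-SB1 rose 17.3-fold (log2 fold change 4.12, SE 0.53, adjusted p = 0.00354). The attacin gene AttD rose 6.19-fold, while PGRP-SC2, whose product degrades peptidoglycan, fell 3.57-fold from 11468 ± 3260 to 3144 ± 18.0. Of 10 measured Imd-responsive effectors 3 rose, 1 fell and 6 were not past the threshold, the same numbers as when adjusted over the list alone (3 and 1). Defensin (Def) was among those not past it, with a log2 fold change of 0.91 and an SE of 0.61 (adjusted p = 0.31), and 0.14 without GFP replicate 1, 1.69 without GFP replicate 2 and 0.50 without Gyc76C replicate 2. The median log2 fold change was 0.30, or 0.46 with centred arrays, and the list passed camera narrowly (adjusted p = 0.0353), but had adjusted p = 0.658 with an estimated correlation. It did not pass without GFP replicate 1 (0.067), without Gyc76C replicate 2 (0.0626), with centred arrays (0.0601), after quantile normalization (0.0641) or with a filter at the 60th percentile (0.131), and 5 members rose without GFP replicate 1.

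Genes that encode the Toll and Imd signalling pathways themselves did not pass camera as groups. Neither did the list of JAK-STAT and stress-induced Turandot genes. Of 18 Toll pathway components 2 rose and 3 fell (2 and 5 adjusted over the list alone), with a median log2 fold change of -0.07 (camera adjusted p = 0.907). SPE, the protease that activates the Toll ligand, rose 2.15-fold, Pli (Pellino) fell 5.11-fold and GNBP3, a sensor of fungal glucan, fell 1.82-fold, although the GNBP3 call ended without Gyc76C replicate 1 (adjusted p = 0.0635). Among 14 Imd pathway components 1 fell, the ubiquitin-conjugating enzyme gene ben with a log2 fold change of -1.08, also 1 when adjusted over the list alone, and the list had adjusted p = 0.707. In the list of JAK-STAT and stress-induced Turandot genes 2 of 5 rose (2 adjusted over the list alone; camera adjusted p = 0.198). These were TotC at a log2 fold change of 2.34 and vir-1 at 0.62, and both lost the call without Gyc76C replicate 1 (adjusted p = 0.0715 and 0.212), as vir-1 did without Gyc76C replicate 2 (0.0976). Without the variance trend GNBP3, TotC and vir-1 were not called (adjusted p = 0.0567, 0.0527 and 0.0762). Over these 3 lists there were 8 calls, counted per list, against 3 without Gyc76C replicate 1, 5 without Gyc76C replicate 2 and 3 without the variance trend.

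**Figure D2:**
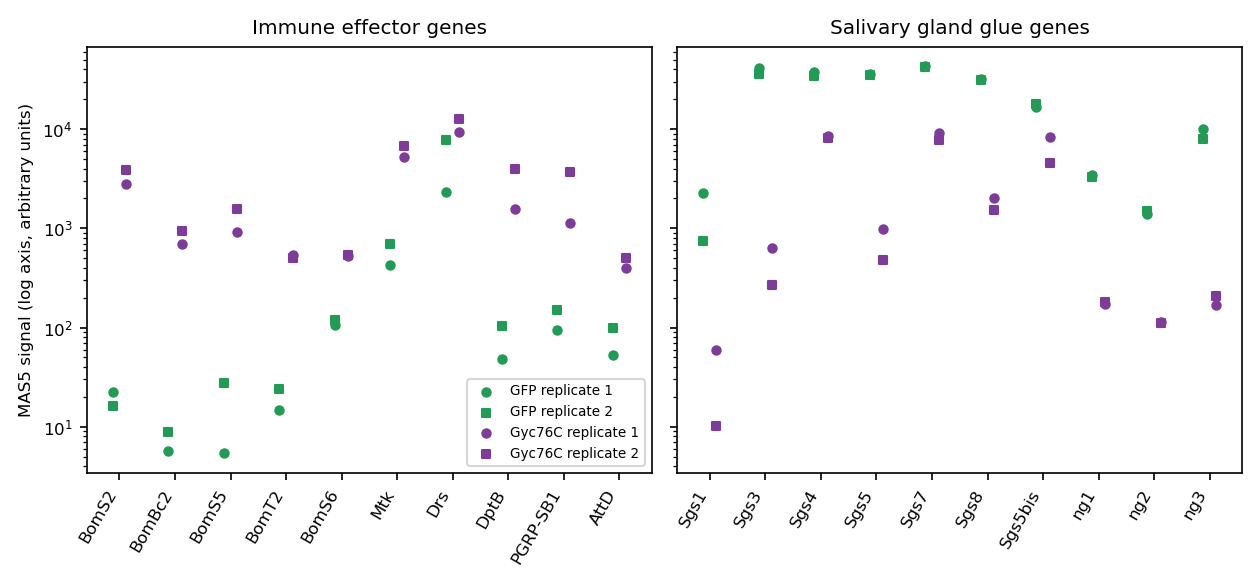
MAS5 signal of each array on a log axis (arbitrary units) for 10 immune effector genes (left) and 10 salivary gland glue genes (right), 1 symbol per array, with GFP larvae in green and Gyc76C larvae in purple. Sgs3 falls from a mean of 38774 in GFP larvae to 449 in Gyc76C larvae, BomS2 goes from 19.4 to 3368, and the 2 GFP signals of Drs, 2310 and 7860, lie far apart.

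The salivary glue genes were among the transcripts that fell most. Sgs3, which encodes a glue protein that fixes the puparium to its substrate, had a signal of 38774 ± 3550 in GFP larvae and 449 ± 254 in Gyc76C larvae, 94.2-fold lower (log2 fold change -6.56, SE 0.36, adjusted p = 0.000175). Sgs5 and ng3 had log2 fold changes of -5.71 and -5.56, and Sgs1 was at least 24.8-fold lower, with 1 of its Gyc76C signals under 46.3. The other glue genes, named after their values were seen, fell less, from -1.49 for Sgs5bis and -2.13 for Sgs4 to -4.27 for ng1, and all 10 glue genes tested fell. Of 16 measured salivary gland markers 12 fell (12 adjusted over the list alone), with a median log2 fold change of -2.40, or -2.24 with centred arrays (camera adjusted p = 6.53e-08). The call had adjusted p = 0.658 with an estimated correlation. Salivary gland genes outside the glue group moved less: the transcription factor gene sage fell by 1.11 on the log2 scale, whereas fkh had -0.11, PH4alphaSG1 -0.49, PH4alphaSG2 0.41 and Pgant9 0.01, none of these 4 past the threshold. These 5 genes were named after their values were seen.

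Genes that respond to the steroid ecdysone fell as a group. Eig71Ee, an ecdysone-induced gene that is also expressed in the salivary gland, fell 5.52-fold from 18821 ± 1050 to 3442 ± 672 (n = 2 each, adjusted p = 0.000395). The transporter gene E23 fell 6.88-fold, with GFP signals of 490 and 1370 and Gyc76C signals of 122 and 116. Of 21 ecdysone response genes 12 fell (14 adjusted over the list alone), with a median log2 fold change of -1.36 and -1.21 with centred arrays (camera adjusted p = 0.000676). The call was lost, at adjusted p = 0.658, with an estimated correlation, and 6 members fell without Gyc76C replicate 1 and 6 without the variance trend. ImpE2 had a log2 fold change of -2.21, and its call ended without that array (adjusted p = 0.0674), while without GFP replicate 2 the value was -1.45. The ImpE2 call also ended without the variance trend (0.0952) and with a robust variance (0.104). All 4 measured genes of the Eig71E cluster belong to the ecdysone list as well. Of these 2 fell (4 adjusted over the list alone), with a median of -2.98, or -2.82 with centred arrays, and camera adjusted p = 0.0353, or adjusted p = 0.658 with an estimated correlation. Without GFP replicate 2 the cluster had an adjusted p of 0.272, 1 member fell, and the call of Eig71Eg, dim in Gyc76C larvae and at least 3.43-fold lower, ended (adjusted p = 0.556); the Eig71Eg call ended as well without GFP replicate 1 (0.0983), after quantile normalization (0.0687) and with signals under 46.3 raised to that level (0.163).

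Many cuticle genes rose in Gyc76C larvae. TwdlN and TwdlP are members of the Tweedle family of cuticle proteins. TwdlP rose 16.7-fold, from 431 ± 177 to 6893 ± 201, and TwdlN rose at least 23.7-fold, from 59.6 ± 39.8 to 1523 ± 269. Lcp65Af, a larval cuticle protein gene, rose 14-fold to 6470 ± 771 (log2 fold change 3.80, SE 0.57, adjusted p = 0.00589, and 0.0542 with a robust variance), and Cpr97Eb and Cpr64Ad had log2 fold changes of 2.71 and 2.61. Cpr49Ab went the other way, with 139 ± 54.6 in GFP and 6.41 ± 4.10 in Gyc76C larvae, and its call ended without either GFP array (adjusted p = 0.0815 without replicate 1 and 0.216 without replicate 2). Of 66 measured members of cuticle protein families 34 rose and 5 fell (38 and 6 adjusted over the list alone), with a median log2 fold change of 1.10, or 1.25 with centred arrays (camera adjusted p = 7.47e-10). Of 25 larval cuticle genes 14 rose and 2 fell (14 and 4 adjusted over the list alone), with a median of 1.32, or 1.48 with centred arrays (camera adjusted p = 1.53e-05). Both lists had adjusted p = 0.509 with an estimated correlation, 23 of the larval cuticle genes tested are also in the first list, and 1 of them fell without Gyc76C replicate 1, with centred arrays or without the variance trend, where 3 of the first list fell.

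Genes of secreted gut and cuticle linings followed. Muc18B and Muc26B, which encode mucins, rose 3.97-fold and 3.25-fold, to 10555 ± 616 and 5769 ± 362. The chitin-binding obstructor genes obst-I and obst-H rose 2.62-fold and 2.21-fold. Of 22 peritrophin and mucin genes 10 rose (13 adjusted over the list alone, with 1 falling), and the median log2 fold change was 0.55, or 0.71 with centred arrays (camera adjusted p = 4.07e-06; adjusted p = 0.658 with an estimated correlation). The number that rose was 6 without Gyc76C replicate 1, 5 without Gyc76C replicate 2 and 5 without the variance trend.

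Mitochondrial genes shifted upward by small amounts in many members. The mitochondrial ribosomal protein genes mRpL13, mRpS30 and mRpS11 rose 2.39-fold, 2.35-fold and 2.19-fold, mRpS30 from 751 ± 8 to 1766 ± 39.1. Of 69 such genes 42 rose (54 adjusted over the list alone), with a median log2 fold change of 0.57, or 0.73 with centred arrays (camera adjusted p = 9.18e-19; adjusted p = 0.509 with an estimated correlation). The number that rose was 5 without Gyc76C replicate 1, 13 without Gyc76C replicate 2 and 11 without the variance trend. Of 22 genes of mitochondrial oxidative phosphorylation 10 rose (12 adjusted over the list alone), with a median of 0.47, or 0.63 with centred arrays (camera adjusted p = 1.32e-06; adjusted p = 0.658 with an estimated correlation). ND-75 of complex I rose 1.84-fold, from 1372 ± 78.6 to 2521 ± 123, and the number that rose was 5 without Gyc76C replicate 1, 3 without the variance trend and 17 after quantile normalization. Cytoplasmic ribosomal protein genes did not pass camera: 1 of 33 rose, RpL34a at 0.58, with a list median of -0.14 and a camera adjusted p of 0.626. By limma 0 members were called when adjusted over the list alone, and 1 rose and 1 fell at an unadjusted p under 0.05. The RpL34a call ended without either Gyc76C array (adjusted p = 0.0693 without replicate 1 and 0.143 without replicate 2) and without the variance trend (0.0924).

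Some muscle and glycolysis genes were also higher. Mlc2, a myosin light chain gene, rose 3.26-fold from 660 ± 110 to 2140 ± 180, and sls and bt, which encode giant titin-like proteins of the sarcomere, rose 3.80-fold and 2.15-fold, although the sls call ended without the variance trend (adjusted p = 0.0539). Of 17 muscle markers 7 rose (9 adjusted over the list alone), with a median log2 fold change of 0.47 and 0.63 with centred arrays (camera adjusted p = 0.000473; adjusted p = 0.658 with an estimated correlation). The number of muscle markers that rose was 4 without the variance trend. The hexokinase genes Hex-C and Hex-A rose 4.33-fold and 2.10-fold, and Gpdh1, the glycerol-3-phosphate dehydrogenase gene, rose 2.00-fold to 21032 ± 910. Of 14 genes in the glycolysis list 4 rose (5 adjusted over the list alone), with a median of 0.39 and 0.55 with centred arrays (camera adjusted p = 0.000809; adjusted p = 0.658 with an estimated correlation). The number of glycolysis genes that rose was 7 without GFP replicate 1.

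Many proteasome genes were lower. Rpn6 fell 1.74-fold, from 6815 ± 1060 to 3887 ± 89.8, and Rpn11, Prosbeta2 and Prosalpha4 had log2 fold changes of -0.78, -0.78 and -0.72. Of 25 proteasome genes 13 fell (18 adjusted over the list alone), with a median of -0.47, or -0.31 with centred arrays (camera adjusted p = 4.7e-05; adjusted p = 0.826 with an estimated correlation). The number of single-gene calls depends on the settings: limma called 6 members with centred arrays and 0 without the variance trend, where 13 had an unadjusted p under 0.05. The calls of Rpn6, Rpn11, Prosbeta2 and Prosalpha4 ended without Gyc76C replicate 1, with log2 fold changes of -0.82, -0.83, -0.79 and -0.81. Those of Rpn11 and Prosalpha4 also ended without Gyc76C replicate 2, with log2 fold changes of -0.73 and -0.64.

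Lysozyme, testis and glycosyltransferase genes made up the remaining lists past the camera threshold. LysS, which encodes a digestive lysozyme, fell 5.26-fold from 22069 ± 5010 to 4144 ± 286, LysP fell at least 3.80-fold, and 2 of 3 lysozymes fell (2 adjusted over the list alone; camera adjusted p = 0.0353, 0.0601 without GFP replicate 2 and 0.658 with an estimated correlation). The lysozyme list had a median log2 fold change of -2.4, or -2.24 with centred arrays. The testis-specific tubulin gene betaTub85D fell 2.59-fold and the sperm gene Mst84Da 2.76-fold. Of 23 testis markers 5 fell (9 adjusted over the list alone), with a median log2 fold change of -0.83, or -0.67 with centred arrays (camera adjusted p = 0.00414; adjusted p = 0.826 with an estimated correlation). For testis markers camera gave 0.067 without GFP replicate 1 and 0.0601 without Gyc76C replicate 1. The number that fell was then 2 and 1, against 8 without GFP replicate 2, 13 without Gyc76C replicate 2, 1 without the variance trend and 8 with the replicate block. The Mst84Da call ended without GFP replicate 1 (adjusted p = 0.0538) and without Gyc76C replicate 1 (0.0839, log2 fold change -0.96 against -1.47), and without the variance trend neither Mst84Da (0.0918) nor betaTub85D (0.0647) was called. Ugt35C1 and Ugt37C2, which encode enzymes that conjugate sugars to small molecules, rose 5.61-fold and 4.21-fold. Of 28 UDP-glycosyltransferases 11 rose and 3 fell (12 and 3 adjusted over the list alone), with a median of 0.21 and 0.36 with centred arrays (camera adjusted p = 0.0353; adjusted p = 0.658 with an estimated correlation). That list did not pass with centred arrays (0.0652), with a filter at the 60th percentile (0.166), with the replicate block (0.0716), without GFP replicate 1 (0.0885) or without Gyc76C replicate 1 (0.0663), where 6 members rose, and 7 rose without Gyc76C replicate 2. Without the variance trend 7 rose and 1 fell.

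**Figure D3:**
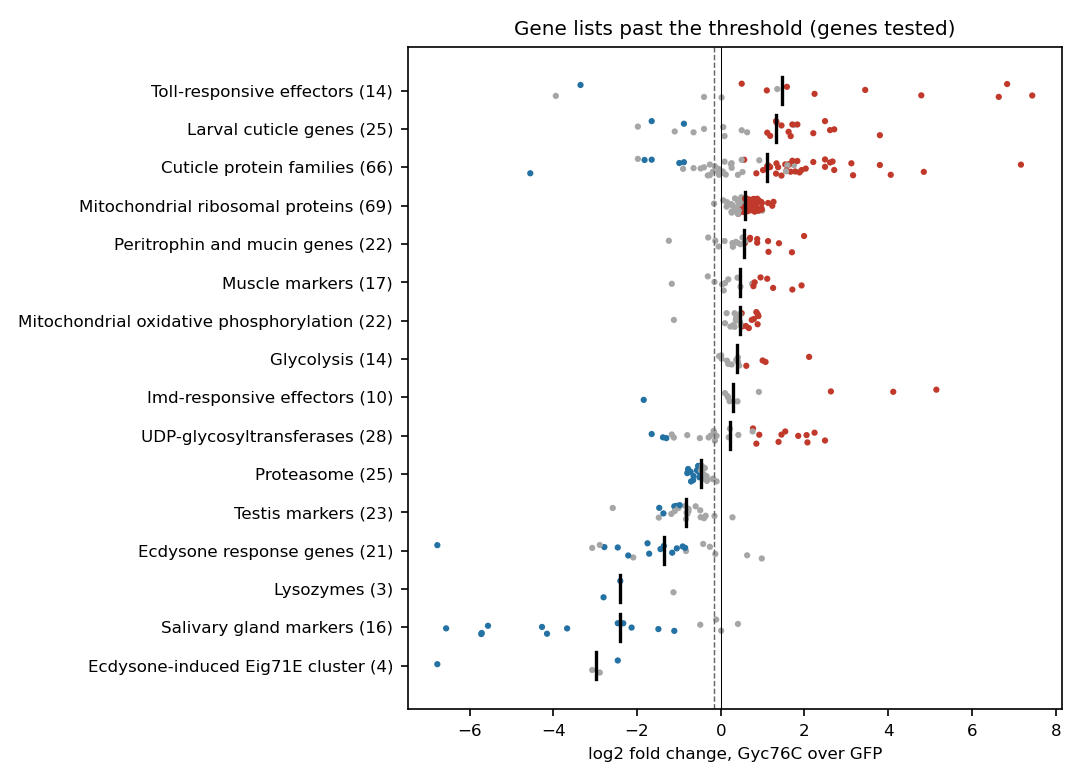
Log2 fold change of each measured gene (horizontal axis) in the 16 lists past the camera threshold, with the number of genes tested after each name; red and blue points are genes past the limma threshold, grey points are not, and black bars are medians. The solid line marks 0 and the dashed line the median of tested genes at -0.17; the list medians run from -2.98 for the Eig71E cluster to 1.47 for Toll-responsive effectors.

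Fat body genes, of the organ in which the transgene was placed, moved apart from one another. Apoltp, which encodes a lipid transfer particle, rose 4.86-fold from 694 ± 64.5 to 3378 ± 410, and the fatty acid synthase gene FASN1 rose 1.80-fold. Fbp1, the receptor for larval storage proteins, fell 2.93-fold from 36644 ± 2880 to 12670 ± 2910, and the lipid droplet gene Lsd-1 fell 2.84-fold. Of 13 larval fat body markers 2 rose and 3 fell (2 and 3 adjusted over the list alone), with a median log2 fold change of 0.04 (camera adjusted p = 0.626). The storage protein gene Lsp2 had -0.37 (adjusted p = 0.147), and Fbp2 at -0.48 was the third to fall, narrowly (adjusted p = 0.0499, and 0.171 with centred arrays), both named after their values were seen. In lipid synthesis and storage 5 of 19 genes rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.185), among them the acetyl-CoA carboxylase gene ACC, 3.06-fold higher, and sug, 2.55-fold higher. The number of these that fell was 4 without GFP replicate 2 and 1 without Gyc76C replicate 1 or without the variance trend.

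Markers of blood cells also went both ways. The collagen IV genes vkg and Col4a1 rose 3.47-fold and 2.47-fold, vkg from 2875 ± 126 to 9976 ± 434, whereas the phagocytic receptor gene crq and the surface protein gene He fell 2.60-fold and 1.98-fold. Of 14 plasmatocyte markers 3 rose and 5 fell (3 and 5 adjusted over the list alone; camera adjusted p = 0.626). In the Nimrod family 1 of 8 rose and 3 fell (1 and 3 adjusted over the list alone; adjusted p = 0.945), with NimC2 5.45-fold lower and NimB2 2.30-fold higher. The prophenoloxidase gene PPO2, which rose 1.70-fold, lost its call without Gyc76C replicate 1 (adjusted p = 0.11) and replicate 2 (0.0537). It was 1 of 2 crystal cell markers out of 3 to rise (2 adjusted over the list alone; camera adjusted p = 0.198). Of 5 lamellocyte markers 1 rose, the integrin gene Itgbn at 0.72 (1 adjusted over the list alone; list adjusted p = 0.583), and its call ended without GFP replicate 2 (0.0928), Gyc76C replicate 1 (0.178) and Gyc76C replicate 2 (0.123), without a filter (0.0691) and with signals under 46.3 raised to that level (0.051). Without the variance trend NimC2 (0.054), PPO2 (0.0992) and Itgbn (0.065) were not called. Melanization and clotting genes had 4 of 15 higher and 3 lower (4 and 3 adjusted over the list alone; list adjusted p = 0.626), including yellow-f, 5.32-fold lower. Without Gyc76C replicate 1 the plasmatocyte markers that fell were 2, those of the Nimrod family 1, and melanization genes had 0 higher and 1 lower; without Gyc76C replicate 2 these numbers were 3, 1, 0 and 2. Crystal cell markers had 0 higher in both cases, and 1 without GFP replicate 2. In both cases limma gave 4 melanization genes and 2 crystal cell markers an upward unadjusted p under 0.05. Over these 5 lists there were 22 calls, counted per list, against 8 without Gyc76C replicate 1, 10 without Gyc76C replicate 2 and 10 without the variance trend.

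Genes of cGMP signalling, the pathway of the overexpressed enzyme, did not pass camera as a group. Of 11 measured members 2 rose (3 rising and 2 falling adjusted over the list alone), with a median log2 fold change of 0.18 (camera adjusted p = 0.626). Pde6, a cGMP phosphodiesterase gene, rose 2.36-fold from 105 ± 29.3 to 243 ± 20, and dnc, which encodes a cAMP phosphodiesterase, rose 1.59-fold. Both calls ended without Gyc76C replicate 1 (adjusted p = 0.0901 for Pde6 and 0.17 for dnc), and that of dnc also without GFP replicate 1 (0.0515) and Gyc76C replicate 2 (0.135) and without a filter (0.0575), and without the variance trend neither Pde6 (0.0549) nor dnc (0.0632) was called. Without Gyc76C replicate 1 limma called 0 members, where 2 rose and 1 fell at an unadjusted p under 0.05; without GFP replicate 1 it called 3 in each direction, and without Gyc76C replicate 2 it called 1 in each.

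Gut and tubule genes changed in both directions. The maltase gene Mal-A3 rose 7.70-fold from 588 ± 38.9 to 4522 ± 302, and LManV, an alpha-mannosidase gene, fell 8.09-fold. Of 38 midgut digestive enzymes 10 rose and 10 fell (12 and 10 adjusted over the list alone), with a median of -0.02, or 0.14 with centred arrays (camera adjusted p = 0.349). Of 22 Jonah and trypsin proteases, 21 of them also in the midgut list, 3 rose and 4 fell (5 and 4 adjusted over the list alone; adjusted p = 0.594), with betaTry 3.59-fold higher and Jon66Cii 4.97-fold lower. Among 12 Malpighian tubule markers 2 rose and 3 fell (3 and 3 adjusted over the list alone; adjusted p = 0.801), with salt 6.02-fold higher and LManVI 9.32-fold lower. Of 69 cytochrome P450 genes 12 rose and 21 fell (12 and 21 adjusted over these genes alone), and the list of 71, which its symbol pattern had widened by the cyclophilin genes Cyp1 and Cyp40, had adjusted p = 0.853. Cyp6a2, a detoxification P450 gene, fell 9.31-fold. Glutathione S-transferases had 9 of 32 higher and 6 lower (10 and 9 adjusted over the list alone; adjusted p = 0.601), with GstD5 5.27-fold lower and GstE9 2.59-fold higher. The overlapping list of oxidative stress and xenobiotic response had 11 of 33 higher and 7 lower (11 and 7 adjusted over the list alone; adjusted p = 0.583), with Cyp6g1 3.31-fold lower. Odorant binding proteins had 3 of 19 higher and 2 lower (5 and 3 adjusted over the list alone; adjusted p = 0.185), with Obp83cd at least 14.3-fold higher. Serpins had 2 of 16 higher and 4 lower (4 and 5 adjusted over the list alone; adjusted p = 0.801), with Spn31A at least 4.34-fold higher. Several of these counts changed when 1 array was left out. Without Gyc76C replicate 1 the number that rose was 5 for the P450 list, 5 for glutathione S-transferases and 4 for the oxidative stress list, and the number that fell was 1 each for Jonah and trypsin proteases, tubule markers and serpins. Tubule markers that fell were also 1 without Gyc76C replicate 2. Without GFP replicate 1 the number that rose was 7 for odorant binding proteins and 5 each for serpins and for Jonah and trypsin proteases. Without GFP replicate 2 oxidative stress genes that fell were 11 and odorant binding proteins 1. Over these 8 lists, which overlap, there were 109 calls, counted per list, against 73 without Gyc76C replicate 1 and 66 without the variance trend.

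Growth, patterning and stress genes did not pass camera as groups. In the E(spl) complex of Notch target genes 4 of 7 fell (5 falling and 1 rising adjusted over the list alone; camera adjusted p = 0.112), with a median log2 fold change of -0.75, or -0.59 with centred arrays, an adjusted p of 0.0137 by the rotation test fry, and E(spl)mdelta-HLH 3.35-fold lower. Of 17 imaginal disc markers 3 fell (2 adjusted over the list alone; adjusted p = 0.185), with a median of -0.55, or -0.40 with centred arrays, and ara 2.09-fold lower. Its call ended without Gyc76C replicate 2 (adjusted p = 0.0527). Of 20 genes of DNA replication and cell cycle 3 fell (3 adjusted over the list alone; adjusted p = 0.511), with the securin gene pim 2.17-fold lower. Of 15 genes of insulin and TOR signalling 3 fell (3 adjusted over the list alone; adjusted p = 0.712), with ImpL2, an inhibitor of insulin signalling, 1.88-fold lower. Neuronal markers had 2 of 12 lower (2 adjusted over the list alone; adjusted p = 0.833), Ace at -0.98 and fne at -0.76. Both calls ended with centred arrays (adjusted p = 0.0544 and 0.0614) and when any array except GFP replicate 1 was left out (0.0694 to 0.147 for Ace and 0.0826 to 0.153 for fne), and neither passed after quantile normalization (0.0684 and 0.0643), without a filter (0.0632 and 0.0561) or without the variance trend (0.0594 and 0.059). Heat shock proteins had 2 of 8 higher and 2 lower (2 and 2 adjusted over the list alone; adjusted p = 0.664), with the mitochondrial chaperone gene Hsp60A 2.21-fold higher and Hsp27 2.41-fold lower, the latter not called without the variance trend (0.0696). Of 15 genes of the unfolded protein response and ER chaperones 1 fell, Ire1 at -0.84 (0 by limma adjusted over the list alone, with 2 lower and 2 higher at an unadjusted p under 0.05; camera adjusted p = 0.489), and its call ended without GFP replicate 2 (0.174) and without Gyc76C replicates 1 and 2 (0.172 and 0.073), with centred arrays (0.0732), after quantile normalization (0.0786), without a filter (0.0763), without the variance trend (0.0737) and with signals under 46.3 raised to that level (0.0529). Actin cytoskeleton and adhesion genes had 4 of 23 higher and 4 lower (4 and 4 adjusted over the list alone; adjusted p = 0.511), and JNK targets had 1 of 5 higher, scaf at 1.09 (2 rising and 1 falling adjusted over the list alone; adjusted p = 0.572). Without Gyc76C replicate 1 the number that fell was 2 in the E(spl) complex and 1 each for imaginal disc markers, replication genes, insulin and TOR genes and actin genes, while 2 actin genes rose. Without Gyc76C replicate 2 it was 1 each for imaginal disc markers, insulin and TOR genes and heat shock proteins, and actin genes had 2 in each direction. Heat shock proteins that rose were 1 without either Gyc76C array. Without GFP replicate 1, 5 imaginal disc markers fell and 2 JNK targets rose, and without GFP replicate 2 the number that fell was 1 for insulin and TOR genes and 2 for actin genes. Over these 9 lists there were 29 calls, counted per list, 7 higher and 22 lower, against 11 calls without the variance trend. With centred arrays 13 were higher and 9 lower. Across the 29 lists that did not pass camera, there were 183 calls, with a gene of several lists counted in each, against 105 without Gyc76C replicate 1 and 99 without the variance trend.

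The camera test thus placed 16 of 45 lists past its threshold, 10 higher and 6 lower. With an estimated correlation 0 lists passed, 3 had an unadjusted p under 0.05, and the rotation test fry, which asks whether a list's own genes move one way, passed 8. Of these, 6 were among the lists that camera called: mitochondrial ribosomal proteins, both cuticle lists, salivary gland markers, UDP-glycosyltransferases and lysozymes. The others were the E(spl) complex and the crystal cell markers. The remaining lists that camera called did not pass fry. Their fry adjusted p ran from 0.0501 for Toll-responsive effectors to 0.292 for testis markers. It was 0.0754 for ecdysone response genes, 0.137 for proteasome genes and 0.261 for Imd-responsive effectors. The lists of gustatory and odorant receptors, histone genes, male dosage compensation RNAs and the Osiris family had 0, 1, 1 and 1 genes tested and were too small for a test.

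Among single genes the largest rise was that of CG13135, with a signal of 7.49 ± 3.64 in GFP larvae and 21189 ± 3910 in Gyc76C larvae, at least 453-fold higher (log2 fold change 11.54, SE 0.34, adjusted p = 3.77e-05). Jig rose at least 256-fold, from 34.8 ± 17.2 to 12022 ± 1680, and CG14419 at least 101-fold to 5484 ± 677, each with its GFP signal under 46.3 set to that level. CG3588, BomBc3 and CG43316 were at least 32.1-fold, 29.6-fold and 13.1-fold higher. TwdlO went from 12.8 and 818 in the GFP arrays to 12900 and 16800, and its log2 fold change was 7.17, or 4.17 without GFP replicate 1. Its call ended without the variance trend (adjusted p = 0.0932) and with a robust variance (0.227). CG12480 and CG14851, dim in GFP larvae, were at least 5.76-fold and 2.70-fold higher. The CG12480 call ended without Gyc76C replicate 1 (adjusted p = 0.416), and that of CG14851 without Gyc76C replicate 1 (0.411), without Gyc76C replicate 2 (0.321) and after quantile normalization (0.0538).

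Among the falls alpha-Est2, a member of the alpha-esterase cluster, went from 3377 ± 1660 to 4.57 ± 1.63, at least 68.4-fold lower (log2 fold change -9.48, SE 0.44, adjusted p = 9.62e-05). CG11893 fell at least 67.3-fold from 3118 ± 60.3, CG7320 at least 26.2-fold and CG1304 at least 20.7-fold. CG32071 fell at least 72-fold, from 3875 ± 245 to 38.0 ± 34.6. The alpha-mannosidase gene LManIII had 1171 ± 247 in GFP larvae and signals of 92.0 and 4.46 in Gyc76C larvae (log2 fold change -5.84, or -3.65 without Gyc76C replicate 2), and its call ended without the variance trend (adjusted p = 0.0782) and with a robust variance (0.129). CG12522 was at least 2.77-fold lower, and its call ended without GFP replicate 1 (adjusted p = 0.154) and replicate 2 (0.271).

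A description free of a variance model gave a similar separation of the genotypes. Sgs3, Jig and Mtk are examples of genes in which both Gyc76C arrays lay at least 2-fold on 1 side of both GFP arrays. This held for 898 probe sets, 460 higher and 438 lower in Gyc76C larvae. The other splits of the 4 arrays into pairs gave 22 and 11. In these splits each pair held 1 GFP and 1 Gyc76C array, so a probe set whose genotypes did not overlap could not be counted. A genotype difference thus lowers these counts, and they do not measure the background that spread between arrays gives. For the split by genotype the number was 1720 without GFP replicate 1 and 1722 without Gyc76C replicate 2, where fewer pairs are compared. The groups did not overlap in 68.3% of probe sets, where chance gives 33.3%. With 3 splits in all, no permutation test of these arrays can give a p under 0.05.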

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

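Tests in this part were planned before the result they measure was seen, with exceptions. The count of Imd-responsive effectors was chosen after it was seen. The search among control probe sets was made with the data in hand. The recount of Fbp1, Fbp2 and Lsp2 with centred arrays was not in the plan.

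Of the 183 control probe sets, 117 were searched, those left after the hybridization and poly-A controls and the sets named AFFX-Dros were set aside, and 2 carried a strong signal in GFP larvae alone. AFFX-Dm-AF292560-1_s_at had a mean signal of 10595 in the GFP arrays and 4.86 in the Gyc76C arrays, and AFFX-Dm-M62653-1_s_at had 14710 and 16.6. The individual signals were 10300 and 10900 against 7.40 and 2.32 for the former, and 14300 and 15100 against 8.49 and 24.6 for the latter. The GFP larvae alone carried the GFP transgene. The sources used here do not name what these probe sets detect, so whether they detect that transgene was not tested.

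The lower signal of the salivary glue genes, with a median log2 fold change of -4.21 over 10 genes, was weighed first. A smaller share of salivary gland RNA argues for a like fall of other gland genes. However, fkh, sage, PH4alphaSG1, PH4alphaSG2 and Pgant9 had a median of -0.11, between -1.11 for sage and 0.41 for PH4alphaSG2, and sage alone was called lower. Gland share is thus argued against as the whole cause, as far as these genes report the gland. The samples are whole larvae, and signal of these genes from other tissues, which could hide a fall, was not separated. Centring each array moved the median of the Sgs genes by 0.16. It moves all probe sets of an array alike, so that value was set by the array medians. The Sgs median was -4.15 as measured, -3.99 with centred arrays and -4.08 after quantile normalization. These values argue against the scaling of the arrays as the whole cause. Younger larvae in the Gyc76C samples may be a candidate explanation. Of Fbp1, Fbp2 and Lsp2, fat body genes that rise late in the instar, 2 were called lower and none higher. The planned criterion, at least 2 lower and none higher, was thus met. In the unplanned recount with centred arrays Fbp1 alone was called, and Fbp2 had a log2 fold change of -0.32 (limma adjusted p = 0.171). Collection at an earlier age and a slower development caused by Gyc76C itself cannot be told apart, because the labels give the instar but no hour. That limit also holds for the ecdysone response genes (12 of 21 lower, 0 higher). It holds as well for the larval cuticle genes (14 of 25 higher, 2 lower). Stage was not tested for these 2 lists.

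The higher immune effectors were weighed second. A larger share of fat body RNA is argued against, since 13 larval fat body markers had a median log2 fold change of 0.04 while the Toll-responsive effectors had 1.47. Signal shared between Bomanin paralogs, whose sequences are alike, is argued against as the whole cause, since 3 of 8 Toll-responsive effectors outside that family were called higher, Mtk at 3.45, SPE at 1.10 and, narrowly, IM33 at 0.50 (adjusted p = 0.0459), but with 1 lower, Drsl2, and a median of 0.26 there, the list's rise lay mostly in its 6 Bomanins, among which shared signal was not tested. Infection of the Gyc76C larvae may also raise such genes, and 3 Imd-responsive effectors (DptB, PGRP-SB1 and AttD) were called higher, but the arrays carry no measure of microbes, so infection and an effect of the transgene cannot be told apart. An effect of Gyc76C on these genes stays open as a hypothesis.

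Genes that were on in 1 genotype and off in the other were weighed last: 14 genes had both signals under 46.3 in 1 genotype and both at or above 463 in the other, 9 of them higher and 5 lower in Gyc76C larvae. The 5 lower were alpha-Est2, CG11893, CG1304, CG7320 and Cyp4p2, and the 9 higher were CG13135, CG3588, CG43316 and 6 Bomanins (BomT2, BomT3, BomS2, BomS5, BomBc2 and BomBc3). The 2 crosses have different UAS parents, so a strain variant under the probes may give such a pattern, but 0 of these genes had a second tested probe set to compare. A linked block of chromosome that differs between the strains could do so too, yet 0 neighbouring pairs were found where the median of 10000 random draws was also 0, with pairs within a gene family, and so among the Bomanins, left out, so the test could not tell a block from none. Jig and CG14851, neighbours on chromosome 3R in a run of higher genes, were not among the 14 genes that this test used. Both explanations and an effect of Gyc76C therefore cannot be told apart here, for want of second probe sets and of neighbours by chance.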

How the results depend on the processing

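All alternatives were planned except the floor at the filter level and the recounts per gene list, which were chosen after the data were seen. Of the 2771 probe sets called, 0 reversed their direction in any alternative fit, with 2493 of them kept by the filter at the 60th percentile. The filter, block and variance settings leave each log2 fold change as it was, so there a reversal was impossible. Leaving out 1 array, adding a constant or raising low signals cannot reverse a probe set whose groups do not overlap. The 0 is thus informative mainly for the 2 other scalings. The Gyc76C level stayed past the threshold throughout, between 4.03 and 4.41 when 1 array was left out. The number of probe sets past the threshold, 2771, ranged from 1204 to 3350 when 1 array was left out, with 575 to 1588 higher and 629 to 1762 lower, and from 12 to 16 lists passed camera over the planned settings with the preset correlation, with 13 to 15 when 1 array was left out. Without the variance trend the count was 1241 (612 higher and 629 lower), with a further threshold of 2-fold it was 1373 (620 and 753), with centred arrays 991 were lower, and at an adjusted p under 0.1 there were 2297 lower; fewer probe sets pass a stricter rule by construction, and for the other changes the cause was not tested. Of the calls under quantile normalization 2341 of 2620 were shared with those reported, and with centred arrays 2262 of 2654, all in the same direction. The count over pairs of arrays, 898, was 570 with 64 added before log2, 1680 with no filter, 2258 at 1.5-fold, 314 at 3-fold, and 1228 to 1722 when 1 array was left out, which follows from the construction of each. With an estimated correlation 0 lists passed, where limma's camera gave 3 an unadjusted p under 0.05. Robust estimation has no setting in camera and was not run for the lists.

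Among 157 named probe sets tested, no call was lost with 16 or 64 added before log2, 13 were lost with centred arrays, 16 after quantile normalization, 16 without a filter, 49 without the variance trend and 7 with robust estimation. Without GFP replicate 1 the calls of 9 were lost, without GFP replicate 2 of 17, without Gyc76C replicate 1 of 47 and without Gyc76C replicate 2 of 30. Raising signals under the filter level to it ended 9 calls. No detection call or background signal was used, so the level of 46.3 stands in for it, and folds against signals under it are given as bounds.

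The labels number the replicates 1 and 2 in both genotypes, but the deviations of same-numbered arrays from their group means correlated at 0.04, and with 2 pairs the numbers are not taken to pair the samples. With the replicate block the fit called 3101 probe sets (1370 higher and 1731 lower), 1132 probe sets in the count over pairs and 15 lists, with a Gyc76C level of 4.22. Drs passed the threshold under the replicate block (adjusted p = 0.00806), and the calls of Tg (0.075) and of the UDP-glycosyltransferases (0.0716) were lost.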

Other observations

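All tests in this part were chosen after the data were seen, and they describe groups by symbol stem or gene order, with some members also in the fixed lists.

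Families of genes with a common symbol stem and at least 6 tested members were compared with the other genes by camera, 96 families in all. The maltase genes Mal-A, which encode enzymes of sugar digestion, had 7 of 8 members higher and 1 lower, with a median log2 fold change of 1.92 (adjusted p = 3.29e-05). Subunit genes of mitochondrial complex I with the stem ND- had 9 of 12 higher and those with ND-B 8 of 11, with medians of 0.68 and 0.72 (adjusted p = 3.33e-05 and 0.00026). Of 8 SmydA- genes, which encode relatives of histone methyltransferases, 4 were higher (median 1.01, adjusted p = 0.00395). Autophagy genes named Atg had 7 of 20 lower, with a median of -0.42 (adjusted p = 0.01), and Mediator subunit genes named MED had 6 of 22 lower, with a median of -0.46 (adjusted p = 0.0458). All medians kept their sign under both other scalings and without any 1 array. The MED genes missed the threshold in each of these settings (adjusted p from 0.0586 to 0.131), so their difference is not secure. Without the first Gyc76C array the counts fell to 3 for ND-, 2 for ND-B, 2 for SmydA-, 2 for Atg and 0 for MED, while the Mal-A counts were the same in all settings. All of these families had adjusted p = 0.827 with an estimated correlation, so the calls rest on the preset one. The Bomanin family had the same value, although 8 of 8 members were higher with a median of 5.72. That version of camera therefore cannot decide with these arrays.

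Neighbouring genes that changed together were listed from their order in assembly Release 6, counting tested genes alone. There were 8 runs of at least 5 neighbours called in the same direction. On chromosome 2R the Bomanin genes BomS4, BomBc2, BomS2, BomT2, BomS5 and BomS6 formed a run of 6, all higher in Gyc76C larvae. On chromosome 3R the Tweedle genes TwdlM, TwdlP, TwdlL, TwdlO, TwdlK and TwdlN formed another run of 6 higher genes, and so did CG31265, CG17475, CG4053, CG31266, CG31267 and CG5246. A run of 5 higher genes on the same arm held Pde6, the cGMP phosphodiesterase gene, beside Jig, CG14851, CG8087 and CG14852. No test of how often chance gives such runs was made. A block of chromosome that differs between the strains was not tested for them either.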
